A study of Solanum lycopersicum with 2 samples.

How the data were processed

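RNA sequencing was performed on young primary leaf of mature tomato plants (Solanum lycopersicum) of the cultivar Ailsa Craig. The 2 libraries came from SlCycB2 overexpression and SlCycB2 RNAi plants, with 1 library per group, and a wild-type library was not analysed here. Per the labels' protocols, total RNA was extracted with TRIzol from frozen leaf and Illumina libraries were prepared. TopHat, a spliced read aligner, is named in the submitters' processing notes without a version or a role. The genome build, the annotation, the counting program, the treatment of reads that map to several places and the use of strand are not given in the sources used here.

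The deposited values are RPKM, reads per kilobase of gene model scaled to the mapped reads of the library, as calculated by the authors and rounded to 2 decimals, per the file headers and the values themselves. One value per library was given for each of 34725 gene models with Solyc identifiers. RPKM fixes the sum of reads rather than the level of any gene, so a shift in the most abundant transcripts moves all others the opposite way. Read totals were not given, and the absolute depth of each library is therefore unknown, as is the counting error of any single value. The relative depth was estimated from the 2589 genes with RPKM of at least 0.3 in both libraries and a mean of at most 1.5, where a value should be a whole multiple of what 1 read is worth. The worth of 1 read in the overexpression library over that in the RNAi library was scanned, and the fit was best at 1.02, where 28.0% of those genes had a ratio within 0.01 (natural log) of a fraction built from whole numbers up to 3, against 3.94% at a typical other value. Within the range scanned, which was limited to values around 1, the fit thus favoured libraries close in depth. A larger difference was not searched for, and a simple multiple of the best value could fit as well.

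Libraries were compared as log2((RPKM + 1) / (RPKM + 1)), overexpression over RNAi, with a pseudocount of 1, among the 19466 genes with a mean RPKM over both libraries of at least 1. This scale understates the difference of low genes. A gene was counted as apart when the ratio was at least 2-fold either way. With 1 library per group there is no replicate error, so no test between conditions and no p-value was computed. Every count describes these 2 libraries. For a gene list, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.

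The deposited table does not pair its identifiers with gene names, and 0 of the 34725 identifiers matched the 41476 genes of the RefSeq table used for names (assembly SLM_r2.1). The planned check of SlCycB2 by name, and 22 of the 25 gene lists planned from gene descriptions, could therefore not be run. The lists not assessed include those for cyclins, mitosis, histones, proteinase inhibitors, jasmonate and pathogenesis-related genes. The other 3 lists were also planned from gene descriptions, and that part could not be applied. In addition they held identifiers written down from general knowledge of tomato genetics before the data were examined. Only these identifiers were used, so each list covers a few loci and not a whole gene family. The gene lists, the thresholds, the rule for named genes and the 8 alternative settings were likewise written down before the data were examined. The link between these identifiers and their functions was not checked against an annotation. The terpene synthase list held Solyc01g105890, Solyc06g059930, Solyc08g005670, Solyc08g005710 and Solyc08g005665, the last of which is not a row of the table used here. The list of BAHD acyltransferases, a family that includes the acylsugar enzymes, held Solyc12g006330, Solyc04g012020, Solyc11g067270 and Solyc01g105580. The list of trichome regulators and HD-ZIP IV factors held Solyc02g080260, Solyc10g078970, Solyc08g005050, Solyc01g010910 and Solyc01g091630.

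The rule for named genes took the 8 largest differences in each direction among the 13541 genes with a mean RPKM of at least 5, and the preset identifiers. As the identifiers carry no names, only the first 2 in each direction are given by identifier and the others as ranges. The alternatives were pseudocounts of 0.1 and 5, rescaling both libraries to the same RPKM sum, centring on the median ratio, scaling by a trimmed mean of ratios (30% of ratios and 5% of levels trimmed at each end), no filter on low values, a mean RPKM of at least 5, and a 4-fold limit. The procedure was tested on simulated data for this comparison over 34725 genes at an assumed depth. Of 100 genes raised 4-fold, 100% were recovered, and of 100 lowered 4-fold, 99% were recovered, with 2 unchanged genes counted as apart. The changed genes all had a mean RPKM of at least 5, and the simulated spread between libraries was small and assumed. These figures check the procedure and do not give the share of false calls in the real data. A simulated depth ratio of 1.1 was recovered as 1.1.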

Results

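Leaf transcriptomes of tomato plants with opposite manipulations of SlCycB2, a B-type cyclin gene, were compared by RNA sequencing. B-type cyclins are regulatory partners of the kinases that drive cells into mitosis. One library was made from overexpression plants and 1 from RNAi plants, in which expression of the gene is meant to be silenced. Both were from young primary leaf of the cultivar Ailsa Craig. The series addresses the part of SlCycB2 in multicellular trichomes, the leaf hairs that carry much of the plant's chemical defence, and in reproductive organs. Without a wild-type library, a difference between the 2 cannot be assigned to either manipulation alone, and without replicates no difference could be set against the spread between plants.

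Transcripts were detected from 23804 of 34725 gene models in the RNAi library and from 23901 in the overexpression library, and 9690 were listed at 0 in both. The median RPKM of detected genes was 6.19 in the RNAi library and 6.99 in the overexpression library. The 10 most abundant genes held 12.4% of the RPKM sum in the RNAi library and 11.03% in the overexpression library. Across the 19466 genes with a mean RPKM of at least 1, log2 levels of the 2 libraries correlated with a Pearson r of 0.96 and a Spearman rho of 0.95. These correlations are across genes, which are not independent replicates.

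The question of how overexpression and RNAi leaves differ was addressed gene by gene. Most genes were within 2-fold, and 506 genes were at least 2-fold higher and 373 at least 2-fold lower in the overexpression library, together 4.52% of the genes compared. At a 4-fold limit the numbers were 96 higher and 99 lower. The extremes were of similar number, with 17 genes at least 16-fold higher and 13 at least 16-fold lower. In all, 131 genes were listed at 0 in the RNAi library and at 1 RPKM or more in the overexpression library, reaching 46.03 RPKM, and 124 showed the opposite pattern, reaching 15.6 RPKM. These sets partly overlap the genes at least 2-fold apart. The balance of directions depended on scaling. The median log2 ratio of all compared genes was 0.13 rather than 0, and genes higher in the overexpression library made up 57.6% of those apart as deposited, 43.4% after centring on that median and 45.4% after scaling by a trimmed mean of ratios.

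**Figure D1:**
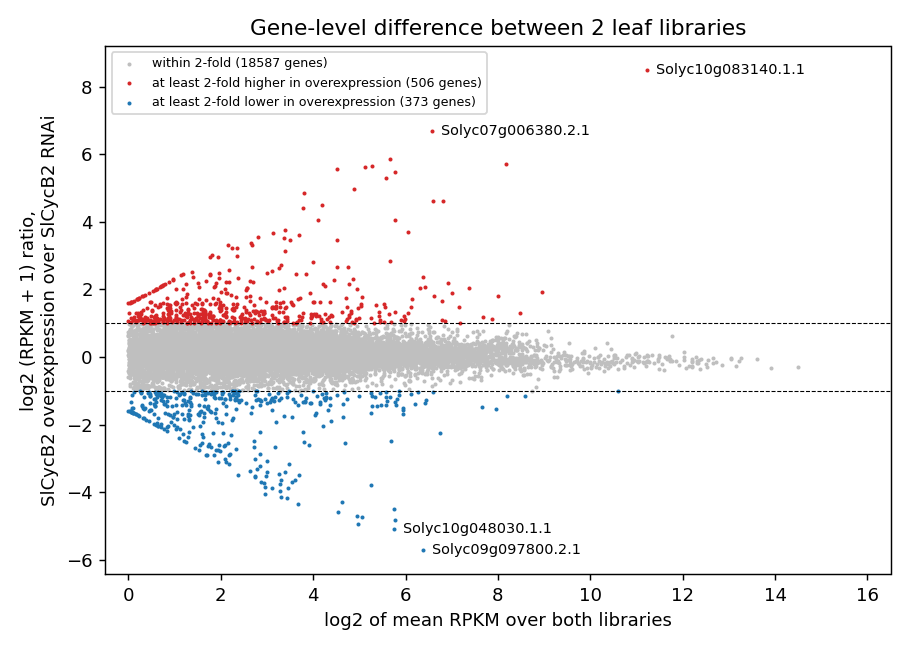
Log2 ratio of RPKM + 1 (overexpression over RNAi, vertical axis) against the log2 of the mean RPKM of both libraries (horizontal axis) for 19466 genes, 1 point per gene, with dashed lines at 2-fold. The 506 genes at least 2-fold higher are red and the 373 at least 2-fold lower are blue, and Solyc10g083140.1.1 lies above every other gene.

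The largest difference of any gene was that of Solyc10g083140.1.1, on chromosome 10 by its identifier. It stood at 12.3 RPKM in the RNAi library and 4816 RPKM in the overexpression library, a ratio of 390 and a log2 difference of 8.50 with the pseudocount. The next was Solyc07g006380.2.1, on chromosome 7, with 0.87 RPKM in the RNAi library and 190.4 RPKM in the overexpression library, a log2 difference of 6.68. The other 6 of the 8 genes with the largest positive differences ranged from 5.48 to 5.86 on the log2 scale. Of these 6 genes, 4 carried chromosome 9 identifiers, all between Solyc09g083440 and Solyc09g089540. All 6 genes lay between 46.03 and 566.6 RPKM in the overexpression library. In the RNAi library they lay between 0 and 9.79 RPKM.

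In the opposite direction the largest difference was that of Solyc09g097800.2.1, on chromosome 9. It was listed at 165.2 RPKM in the RNAi library and 2.15 RPKM in the overexpression library, a log2 difference of -5.72. Solyc10g048030.1.1, on chromosome 10, followed with 105.4 RPKM against 2.12 RPKM, a log2 difference of -5.09. The other 6 of the 8 genes with the largest negative differences ranged from -4.93 to -4.49 on the log2 scale. They had 45.2 to 107.3 RPKM in the RNAi library and 0.93 to 3.69 RPKM in the overexpression library. The file does not pair any of these identifiers with a name, so what the genes encode is not given, and SlCycB2 itself was not checked by name.

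Terpene synthases are the enzymes that make volatile terpenes in glandular trichomes and other tissues. Of the 5 loci fixed in advance as terpene synthases, 4 were in the table, of which 3 were at least 2-fold lower in the overexpression library and 1 was at least 2-fold higher. The 3 lower loci were at 19.65, 14.4 and 4.18 RPKM in the RNAi library and at 0.16, 0.18 and 0.19 RPKM in the overexpression library. Their log2 differences were -4.15, -3.71 and -2.12. The remaining locus went from 2.14 RPKM in the RNAi library to 7.54 RPKM in the overexpression library, a log2 difference of 1.44. The median of the list was -2.91, and 0% of 10000 random lists matched on expression had a median as low. The central 95% of those medians lay between -0.28 and 0.55. This percentile describes these 2 libraries only, and the random lists drew each gene independently. Solyc08g005670 and Solyc08g005710 lie close by identifier, and neighbouring identifiers were apart together more often than shuffled genes. The percentile may therefore overstate how unusual the list is. The size depended on the pseudocount: with 5 in place of 1, 2 loci were at least 2-fold lower and 0 higher and the median was -1.36, and with 0.1 the median was -4.79. The function of the locus at 14.4 RPKM, Solyc08g005670, was the least certain, and without it, an alternative added after the data were seen, the median was -2.12.

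The 4 loci fixed in advance as BAHD acyltransferases of acylsugar synthesis, the pathway of the sticky sugar esters secreted by glandular trichomes, all had lower RPKM in the overexpression library, although 3 were near the floor. Only 1 reached a mean RPKM of 1. It was at 5.77 RPKM in the RNAi library and 0.32 RPKM in the overexpression library, a log2 difference of -2.36, and 0.78% of random matched genes were as low. That difference was -3.80 with a pseudocount of 0.1 and -1.02 with 5. The other 3 were at 0.62, 0.64 and 1.52 RPKM in the RNAi library and were listed at 0 in the overexpression library.

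Among the 5 loci fixed in advance as trichome regulators and HD-ZIP IV factors, a class of plant transcription factors, the 3 with a mean RPKM of at least 1 were slightly higher in the overexpression library and within 2-fold. They were at 7.22, 11.7 and 23.0 RPKM in the RNAi library and at 9.53, 14.9 and 29.8 RPKM in the overexpression library. Their median log2 difference was 0.36, at percentile 87.5 of the random lists, and 0.21 after scaling by a trimmed mean of ratios. Another of the 5 loci was at 1.22 RPKM in the RNAi library and listed at 0 in the overexpression library, and the last was listed at 0 in both.

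**Figure D2:**
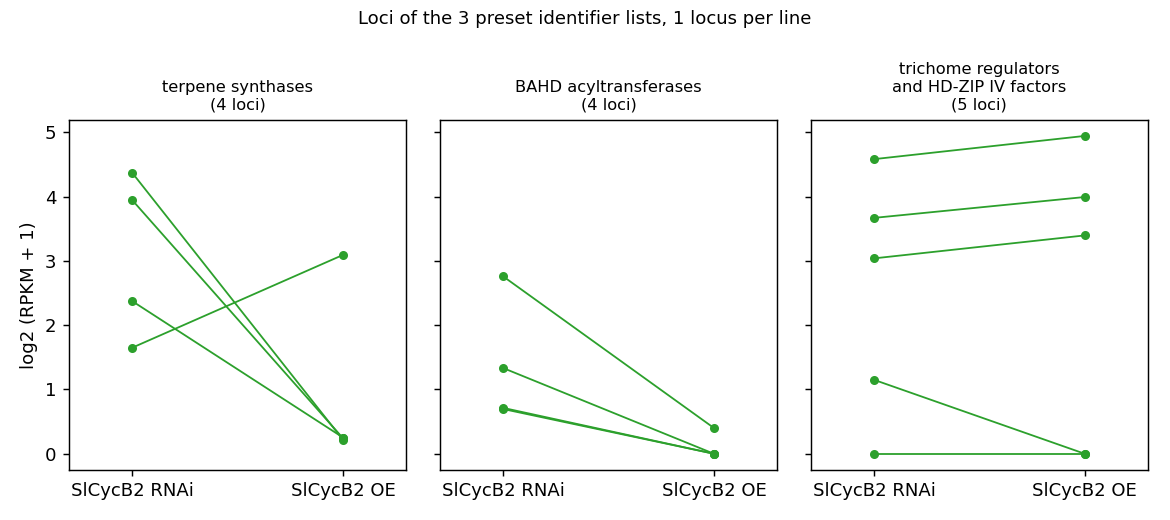
Log2 of RPKM + 1 (vertical axis) in the RNAi and overexpression (OE) libraries for the loci of the 3 preset identifier lists, with 1 line per locus joining its 2 values. Of the 4 terpene synthase loci 3 slope down, the 4 BAHD loci slope down, and the 3 loci of the trichome regulator and HD-ZIP IV list with a mean RPKM of at least 1 slope slightly up. Another locus of that list slopes down, from 1.22 RPKM in the RNAi library to 0 in the overexpression library, and the last is at 0 in both.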

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

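The counts of genes at least 2-fold apart moved with the pseudocount and the filter, while the direction of the preset lists did not reverse under any of the alternatives run. With a pseudocount of 0.1 the counts were 901 higher and 573 lower, and with a pseudocount of 5 they were 141 and 128. At a mean RPKM of at least 5 they were 222 and 155, with fewer genes tested, and at the 4-fold limit 96 and 99. Centring on the median gave 369 and 482, the trimmed mean of ratios 366 and 441, rescaling to the same RPKM sum 540 and 376, and no filter 614 and 481. Of the 506 higher genes 366 kept their side of the limit under the trimmed mean, which lowered ratios by 0 to 0.15 (log2, median 0.14), and of the 373 lower genes 373 did. The median log2 difference of the terpene synthase list was -4.79 with a pseudocount of 0.1, -1.36 with 5, and -3.93 at a mean RPKM of at least 5, where 2 loci remained. With a pseudocount of 5, 1 lower and 1 higher locus of that list came within 2-fold, which left 2 lower. Without Solyc08g005670, an alternative chosen after the data were seen, the median of that list was -2.12. The BAHD list, which rests on 1 locus, was at -3.80 with a pseudocount of 0.1, -1.02 with 5, and -1.02 for all 4 loci without the filter. At a mean RPKM of at least 5 it had no member left. Of 60 values for 12 named loci under the alternatives, 13 moved by more than 1 SD of genes at a similar level and 0 reversed. A change of pseudocount cannot change the sign of a ratio. The rescalings shifted ratios by about 0.15 at most (log2), and the smallest difference of a named locus was 0.32. The lack of reversals, for these loci and for the lists, was thus largely fixed in advance. The SD used for that count was taken across genes of these 2 libraries. It serves as a scale only and does not measure the missing replicate spread. Depth was not given, so counting error could not be separated from other differences. The SD of the log2 ratio was 0.62 in the tenth of genes with the lowest mean RPKM, 0.41 at 18.4 to 28.4 RPKM, 0.53 at 28.4 to 57.6 RPKM and 0.49 above that. No replicate could be left out with 1 library per group. No paired analysis was possible because the comparison has a single library on each side.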

Other observations

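The analysis of neighbouring identifiers was chosen after the data were seen, as were the test on the list of trichome regulators and HD-ZIP IV factors and the search for the name of the gene with the largest difference, whereas the tests of neighbours at higher levels, of shared reads and of the region around that gene were written down before their results. Genes that were apart lay next to each other more often than shuffled genes did. Among pairs of neighbouring identifiers on chromosomes 1 to 12, 45 pairs were both at least 2-fold higher in the overexpression library and 34 were both at least 2-fold lower. In 1000 shuffles of the calls among genes of similar level, the median was 9 pairs higher and 5 pairs lower, and the highest were 18 and 13. Runs of 3 or more neighbours held 29 genes in 9 runs on the higher side, and 6 genes in 1 run on the lower side. That lower run, on chromosome 11 from Solyc11g021260 to Solyc11g021310, was at 15.1 to 124.0 RPKM in the RNAi library and 6.67 to 47.2 RPKM in the overexpression library. On chromosome 9, 11 of the 13 identifiers from Solyc09g083440 to Solyc09g089540 were at least 2-fold higher, at 2.90 to 200.5 RPKM in the overexpression library and 0 to 43.1 RPKM in the RNAi library, and 0 were lower. Both stretches were chosen after their values were seen. By chromosome, the share of compared genes at least 2-fold higher was lowest on chromosome 3 (1.79%) and highest on chromosome 9 (3.58%), unanchored identifiers left aside. The rank of chromosome 9 is not separate from its stretch, which held 11 of its 51 higher genes, and chromosome 10 was close at 3.33%.

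Counting noise at low levels was tested as a source of the neighbouring pairs by keeping genes with a mean RPKM of at least 10. There, 12 pairs were higher and 9 were lower, against at most 4 for each direction in the shuffles. For the higher pairs this argues against noise as the whole source. Part of these higher pairs came from a run of 4 genes on chromosome 9, at 47.3 to 107.1 RPKM in the overexpression library. The run of 6 lower genes on chromosome 11 lay wholly at these levels and supplied most of the lower pairs. At these levels the lower excess thus rests largely on 1 run, so the test does not decide on noise for the lower pairs in general. Among all compared genes, 34 pairs were lower against at most 13 in the shuffles. Lower runs of 3 or more held only 6 genes, so that wider excess does not rest on the run alone. Reads shared between near-identical copies would give pair members close levels. The median absolute log2 difference within pairs was 0.98 for higher pairs (95% bootstrap range 0.58 to 2.12) and 1.07 for lower pairs (0.78 to 1.41). The bootstrap ranges were added after the medians were seen and treated pairs as independent. Pairs within a run share genes, so the bootstrap ranges may be too narrow. Random pairs of higher genes gave 0.83 to 1.85 and random pairs of lower genes 0.78 to 1.96. These ranges include both small and large differences, so shared reads and a common response of neighbouring genes cannot be told apart without the sequences. Whether the neighbours are gene copies is not known, and other sources of these pairs were not tested.

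Solyc10g083140.1.1 had the largest difference of any gene compared. A regional change was argued against by its 20 nearest compared identifiers, whose median log2 ratio was 0.017 and whose largest absolute ratio was 0.70. An introduced overexpression construct would raise its gene without the chromosomal neighbours, so this identifier may be the overexpressed SlCycB2. That remains a hypothesis, since the reference table used here paired the identifier with a name 0 times, and a single strongly responding gene would look alike.

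The 3 lower terpene synthase loci raise the hypothesis that the overexpression leaf held fewer glandular trichomes, or trichomes with lower output, than the RNAi leaf. The remaining terpene synthase locus runs against it, at 2.14 RPKM in the RNAi library and 7.54 RPKM in the overexpression library. The 4 BAHD loci had lower RPKM in the overexpression library, with a log2 difference of -2.36 for the 1 locus above a mean RPKM of 1 and the other 3 near the floor. In the preset list of trichome regulators and HD-ZIP IV factors, 0 of the 3 compared loci were at least 2-fold apart. Their median log2 difference was 0.357, or 0.214 after the trimmed mean of ratios, within the central 95% of random lists (-0.24 to 0.51), while another of its loci, near the floor, was at 1.22 RPKM in the RNAi library and listed at 0 in the overexpression library. Other leaf cells can also express such factors, so this does not decide the matter, and the hypothesis stays open. A change in the number of trichomes and a change in expression within them cannot be told apart from whole-leaf RNA, variation between plants was not measured with 1 library per group, and the functions of these loci were not checked against an annotation.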
